A study of Caenorhabditis elegans with 6 samples.

How the data were processed

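Poly(A) or depletion steps, the sequencer and the read length of these libraries are not given in the sources used here. RNA was taken from whole worms with TRIzol, and libraries were built with a VAHTS Universal V10 RNA-seq kit, per the labels' protocols. The 6 samples fall into 2 groups of 3 by their titles, with or without jellyfish treatment, and that is the single comparison made. Titles and the treatment field agree, but the library names of the untreated samples begin with the letter of the peptide's code in the protocol. An exchange of the labels of the 2 groups would turn the sign of every fold change, and nothing in the files tests it.

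The authors deposited a table of raw read counts per gene and a table of FPKM values, per the file headers, with 1 file of each kind per sample as well. The aligner, the counting program, its strand setting and the annotation version are not given in the sources used here. The submitters' processing notes name GRCm38 and mm10, which are mouse builds, while the gene identifiers are those of C. elegans, so no coordinates are printed. The 6 sample files of counts and the 6 of FPKM equal their columns of the series tables. The deposited FPKM values were checked against the counts: of 98526 values above 0, all but 2 gave 1 whole-number length per gene within 0.001 bases when FPKM was taken as the count scaled by gene length and by the summed counts of the library. Each series table holds 2 more columns of values that match no sample in the labels, and they were not used. Of 18271 gene identifiers, 18242 matched a locus tag of the RefSeq annotation of WBcel235, used here for current names and for which genes are neighbours, and 29 did not.

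Counts were analysed in R 4.3.3 with edgeR 4.0.16, on TMM-normalised libraries and genes kept by filterByExpr (14654 genes, leaving out 3617), with glmQLFit and glmQLFTest on group. Log2 fold changes are treated over untreated, with a standard error taken from the estimate and its F statistic, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM are read counts scaled to the TMM-adjusted library size. Gene sets were tested on log2 CPM (prior count 2) with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, in limma 3.58.1, over 35 lists and over 134 classes of at least 10 genes that share a locus-name prefix. Fry's directional p tests whether the genes of a set move 1 way on balance, and it does not compare the set with other genes. DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), other normalisations and filters, a replicate block and fits without each library in turn were the alternatives chosen before the data were examined. Fits added after seeing the data were robust edgeR, limma-voom with sample weights, DESeq2 without each library in turn, and limma-voom and robust edgeR without untreated replicate 2. Enrichment of DESeq2 calls in the deposited GO and KEGG terms (10 to 500 members) was also added after seeing the data, with a hypergeometric test against annotated genes that had a DESeq2 adjusted p. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

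The genes named follow a rule set before the data were examined: the 8 highest and the 8 lowest fold changes among genes past the threshold with a mean CPM of at least 5 and no overlap between groups, up to 4 members of each list with 2 or more members past it, and 16 readout genes whatever their result. Since 0 genes passed, the 10 genes with the smallest unadjusted p took the first place, as the rule provides. Applying the same rule to the DESeq2 calls, and naming the 16 genes that passed in edgeR without untreated replicate 2, was decided after seeing the data. acdh-1, a readout gene, had 5 reads in all and was not tested.

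The scripts were tested on simulated counts drawn from the real means, library sizes and fitted spread, with 200 genes changed. Each gene was drawn on its own, so no simulated library stood apart as a whole, as untreated replicate 2 did in the real data. The shares recovered therefore need not hold in the real fits. With 14392 genes tested, edgeR recovered 22.4%, 95.5% and 100% of genes changed 2-, 4- and 8-fold with 10 false calls, DESeq2 47.8%, 98.5% and 100% with 73, and limma-voom 22.4%, 94% and 100% with 5. DESeq2 thus called more unchanged genes than its threshold allows at this spread. A simulated set of 60 genes moved 1.5-fold, also drawn gene by gene, passed camera with the preset correlation and with an estimated one (adjusted p = 1.35e-23 and 0.0254). The estimated form thus gave a far larger p even for genes drawn independently. A call lost with it need not reflect correlation between genes.

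Total counts of 31447571 to 41112668 per library mean that 3 reads, the upper limit a count of 0 allows, correspond to 0.073 to 0.0954 CPM. Intervals and limits from counts cover counting error alone. Every pair of libraries differed by far more than sampling noise, so none was counted as a repeat of another.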

Results

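Whole worms of the nematode Caenorhabditis elegans were profiled by RNA sequencing with or without a peptide preparation made from jellyfish. The series asks whether a jellyfish peptide hydrolysate improves health in ageing worms, and this comparison asks which transcripts differ between treated and untreated animals. There were 3 libraries from treated worms and 3 from untreated worms. Treated plates received 100 µL of a 50 mg/mL peptide stock mixed into the bacterial food, and worms at the L4 stage, the last larval stage, were moved to the plates 24 h later. The time of harvest is not given in the sources used here. Total counts over 18271 genes were 41112668, 39433084 and 31447571 in untreated replicates 1, 2 and 3, and 40129035, 40389855 and 38193498 in jellyfish replicates 1, 2 and 3. The most abundant transcript in each library was eef-1A.1, a translation elongation factor, at 1.15% to 1.73% of counts. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

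In treated worms, transcripts of the fatty acid desaturase genes fat-5 and fat-7 were lower, while the infection response genes irg-4 and irg-5 and several cytochrome P450 genes were severalfold higher. fat-5 stood at 40.2 ± 7.81 CPM (read counts scaled to library size; SD, n = 3) in untreated and 11.7 ± 2.3 in treated worms, and irg-5 at 32.6 ± 11.99 and 243 ± 55.4. In a set test with a preset correlation between genes, the sperm, oocyte, yolk and fat synthesis lists were lower in treated worms and the neuronal, muscle and histone lists higher, and 0 of these calls held with the correlation estimated from the data (adjusted p = 0.168 to 0.584). With all 6 libraries edgeR called 0 genes (1429 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 169, and 1 untreated library, replicate 2, stood far from the rest.

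With edgeR's quasi-likelihood test, 0 of 14654 tested genes had a Benjamini-Hochberg adjusted p under 0.05, while 1429 had an unadjusted p under 0.05, where 733 are expected with no difference. The excess was not stable. Without jellyfish replicate 2, 613 genes had an unadjusted p under 0.05, below the 751 expected. The number was 923 without jellyfish replicate 1 and 2376 without untreated replicate 2. DESeq2 on the read counts of all 6 libraries called 169 genes, of which 76 were higher and 93 lower in treated worms and 133 differed by more than 2-fold. limma-voom called 0 genes. Without untreated replicate 2, edgeR called 16 genes, 14 higher and 2 lower, of which 12 were shared with the DESeq2 calls, all in the same direction. DESeq2 called 618 genes without untreated replicate 2, 402 without untreated replicate 3, 59 without jellyfish replicate 2 and 80 without jellyfish replicate 3. In simulated libraries with each gene drawn on its own at its fitted spread, DESeq2 made 73 false calls and edgeR 10. There edgeR recovered 22.4% of the genes changed 2-fold and 95.5% of those changed 4-fold. No simulated library stood apart as untreated replicate 2 did, so these shares need not hold in the real fit. In that fit irg-4, with a log2 fold change of 3.07, had adjusted p = 0.295 in edgeR. The CPM of the 3 treated and the 3 untreated libraries did not overlap for 2910 genes, 19.9% of those tested, where chance gives 10%.

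The list of 30 tested genes for fatty acid synthesis, desaturation, elongation and triglyceride assembly had a median log2 fold change of -0.34, and 7 members were above 0. The list passed camera's set test with a preset correlation at adjusted p = 0.00047, but not with the correlation estimated from the data (adjusted p = 0.457). Its median lay below the untreated range in jellyfish replicate 1 (-0.49, against -0.24 to 0.11 in the untreated libraries), while jellyfish replicates 2 and 3 (-0.08 and -0.18) lay inside it. The median fold change was -0.17 without untreated replicate 1 and -0.22 without jellyfish replicate 1, and the set test with a preset correlation passed in each of the 6 fits that left out 1 library. Over all genes tested, 0 members passed in edgeR, 4 passed adjusted over the list alone, all lower, and DESeq2 called the same number. Adjusted over the list alone, 1 member passed without untreated replicate 1 or 3 or jellyfish replicate 1 or 3, and 6 lower and 2 higher members passed without untreated replicate 2. The 4 members were fat-5 and fat-7, which encode delta-9 fatty acid desaturases, elo-5, an elongase used for branched-chain fatty acids, and dgat-2, an acyltransferase of triglyceride synthesis. The DESeq2 calls of fat-5 and fat-7 passed in each of the 6 fits that left out 1 library, that of elo-5 in 4 (not without untreated replicate 1 or jellyfish replicate 3, adjusted p up to 0.117) and that of dgat-2 in 2 (not without untreated replicate 1 or any jellyfish replicate, adjusted p up to 0.303). The log2 fold changes were -1.78 ± 0.22 (SE) for fat-5, -1.52 ± 0.29 for fat-7, -0.90 ± 0.19 for elo-5 and -1.18 ± 0.29 for dgat-2. DESeq2 gave adjusted p = 4.18e-09 for fat-5 and 0.000845 for fat-7, and edgeR without untreated replicate 2 gave adjusted p = 0.0231 and 0.0419. fat-6, another delta-9 desaturase gene, had a log2 fold change of -1.33 ± 0.50 that rested on untreated replicate 2, at 1344 CPM against 407 and 399 in its group mates, and was -0.50 ± 0.18 without it. Among the KEGG pathways in the deposited annotation, biosynthesis of unsaturated fatty acids held 3 of the DESeq2 calls that were lower, out of 23 members, with 0.0681 expected (hypergeometric adjusted p = 0.00278 over 101 pathways). The 3 were elo-5, fat-5 and fat-7, described above, so the pathway is not separate evidence. Only 7 of the lower calls were in the annotated background. The list of lipases and beta-oxidation genes did not pass (46 genes, median 0.05, adjusted p = 0.285). Among its members, acs-2, an acyl-CoA synthetase, had a log2 fold change of 0.62 ± 0.21, the lipase gene lipl-4 0.26 ± 0.27 (0.04 without untreated replicate 1 and 0.40 without untreated replicate 3) and the triglyceride lipase gene atgl-1 -0.00391 ± 0.13.

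**Figure D1:**
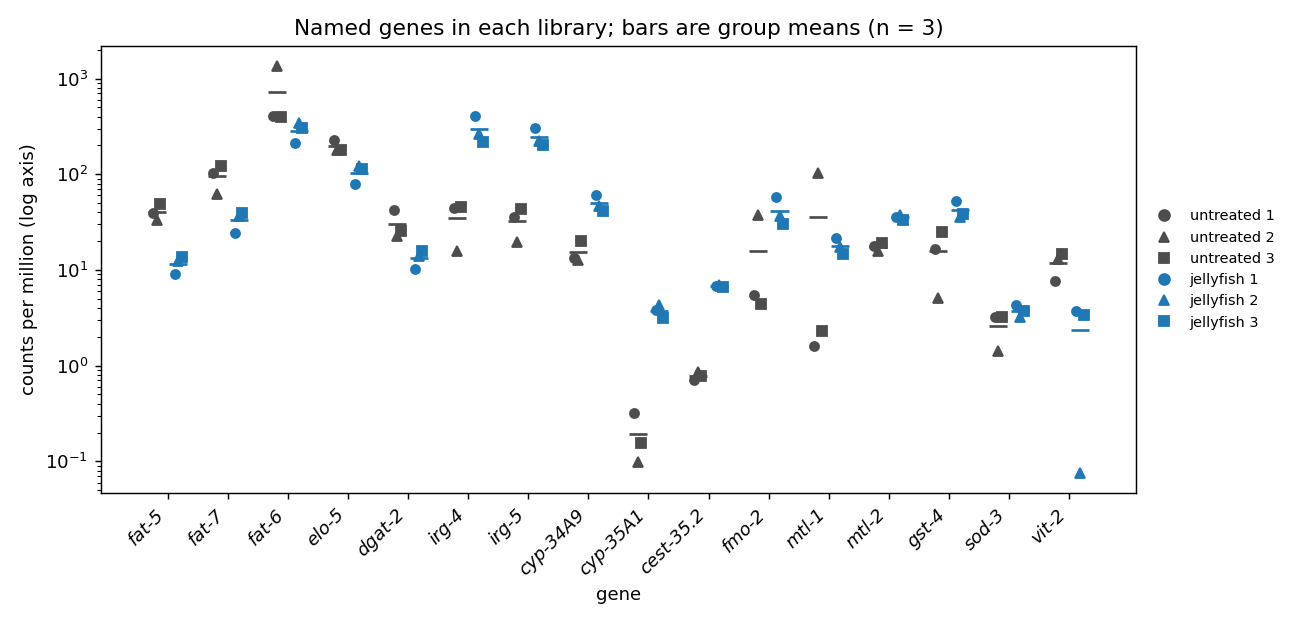
CPM of 16 named genes in each library, on a log axis, with untreated libraries in grey, jellyfish libraries in blue, a symbol for each replicate number and a bar at each group mean (n = 3). The treated libraries lie below the untreated ones for fat-5 and fat-7 and above them for irg-4 and irg-5, while untreated replicate 2 sits with or above the treated libraries for fmo-2 and mtl-1.

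Single genes of pathogen response and of the metabolism of foreign compounds were called by DESeq2. irg-4 and irg-5, which respond to bacterial infection in the intestine, had log2 fold changes of 3.07 ± 0.46 and 2.90 ± 0.33. Of 58 tested antibacterial and pathogen response genes, 0 passed in edgeR over all genes, 5 passed adjusted over the list alone (3 higher, 2 lower), and DESeq2 called the same numbers. Adjusted over the list alone, 7 higher and 4 lower members passed without untreated replicate 2, 2 higher and 0 lower without jellyfish replicate 1 or 3, and 3 higher and 1 lower without untreated replicate 1. The other higher gene was clec-52, a C-type lectin gene named after its values were seen, and the lower ones were spp-9, a saposin-like protein gene (log2 fold change -2.73 ± 0.53), and dod-24 (-1.65 ± 0.30). The list had a median of 0.03 and did not pass the set test (adjusted p = 0.201). Among 64 tested cytochrome P450 genes, 0 passed over all genes in edgeR and 6 passed adjusted over the list alone, all higher. This count was 12 higher and 1 lower without untreated replicate 2, 2 higher without jellyfish replicate 1 and 3 higher without untreated replicate 1 or jellyfish replicate 2 or 3. DESeq2 called 6 as well, namely cyp-14A2, cyp-14A3, cyp-34A9, cyp-34A10, cyp-35A1 and cyp-35A2, of which cyp-14A2 and cyp-35A2 were named after their values were seen. The 6 lie as neighbouring pairs with a shared name prefix, and such copies may share reads. They are therefore not 6 independent results. cyp-34A9 stood at 15.3 ± 4.06 CPM in untreated and 49.6 ± 10.5 in treated worms, and cyp-35A1 at 0.191 ± 0.114 and 3.77 ± 0.596 (SD, n = 3). The P450 list had a median log2 fold change of 0.19 and adjusted p = 0.0164 in the set test, 0.457 with an estimated correlation and 0.226 without untreated replicate 1, where its median was 0.03. The median was 0.12 without jellyfish replicate 1. The carboxylesterase gene cest-35.2 had the smallest p of all genes, with 0.786 ± 0.0782 CPM in untreated and 6.78 ± 0.212 in treated worms, a log2 fold change of 3.10 ± 0.24 and adjusted p = 0.0638 in edgeR. In edgeR without 1 library its adjusted p was 0.0141 without untreated replicate 2 and from 0.181 to 0.816 in the others. Terms of the gene ontology enriched among the DESeq2 calls that were higher included aromatase activity, with 5 of 44 members (hypergeometric adjusted p = 0.00103). All 5 are among the P450 calls above. Carboxylic ester hydrolase activity held 5 of 49, cest-35.2 among them (hypergeometric adjusted p = 0.00119). Both terms hold neighbouring copies, cyp-14A2 and cyp-14A3 and cyp-35A1 and cyp-35A2 in the first, cest-35.1 and cest-35.2 in the second. The test counts such copies as separate genes.

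The genes with the next smallest p in edgeR, none of which passed, were R02C2.7, C33H5.2, F49C12.4, T04A6.1, scl-12 and mtl-2, beside irg-5, cyp-35A1 and fat-5 described above. Without untreated replicate 2, edgeR called R02C2.7, C33H5.2 and F49C12.4 (adjusted p = 0.0231, 0.0475 and 0.0475). No other edgeR fit that left out 1 library called R02C2.7, C33H5.2, F49C12.4, T04A6.1, scl-12 or mtl-2. DESeq2 called all of these in each fit that left out 1 library. Treated worms had 63.7 ± 8.07 CPM of R02C2.7 against 18.6 ± 3.07 in untreated worms, and 35.5 ± 1.88 CPM of mtl-2, a metallothionein gene, against 17.5 ± 1.62 (SD, n = 3). C33H5.2 and F49C12.4 were near the detection limit in untreated worms, at 0.0411 ± 0.0376 and 0.0574 ± 0.0789 CPM, and at 2.91 ± 0.417 and 5.41 ± 1.39 in treated worms. scl-12, a gene for a secreted cysteine-rich protein, had 1 read in the untreated libraries together and 335 in the treated ones, a ratio of 323 with a 95% counting interval of 57.6 to 12800. It stood at 5.12, 1.19 and 2.18 CPM in jellyfish replicates 1, 2 and 3. Its log2 fold change was 7.88 with all libraries and 7.135 without jellyfish replicate 1. T04A6.1 had a log2 fold change of 1.21 ± 0.16.

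Among readouts of longevity and stress pathways, most differences were small against the spread. sod-3, a superoxide dismutase gene controlled by the FOXO factor DAF-16, stood at 2.62 ± 1.05 CPM in untreated and 3.75 ± 0.542 in treated worms (log2 fold change 0.52, and 0.22 without untreated replicate 2). daf-16 itself had a log2 fold change of -0.29 ± 0.21, which was -0.04 without untreated replicate 2 and -0.18 without jellyfish replicate 3. Of 22 tested genes raised by DAF-16, 0 passed over all genes and 3 passed adjusted over the list alone. These were mtl-2 (log2 fold change 1.02 ± 0.14) and icl-1 of the glyoxylate cycle (0.77 ± 0.15), which were higher, and fat-5, which was lower. Adjusted over the list alone, 10 higher members passed without untreated replicate 2 and 1 higher member without jellyfish replicate 1. DESeq2 did not call icl-1 without jellyfish replicate 1, 2 or 3 (adjusted p up to 0.293). The list had a median of 0.22 and adjusted p = 0.0189 in the set test, 0.457 with an estimated correlation and 0.23 without untreated replicate 1, where its median was 0.02. The median was 0.52 without untreated replicate 2. Of 10 tested genes lowered by DAF-16, 0 passed over all genes, and dod-20 (-2.41 ± 0.51) and dod-24 passed adjusted over the list alone, the set test giving adjusted p = 0.0679. DESeq2 did not call dod-20 without jellyfish replicate 2 (adjusted p = 0.104), where 1 member passed adjusted over the list alone, against 3 without untreated replicate 2. mtl-1, the other metallothionein gene, had a log2 fold change of -0.99 ± 1.40 with all libraries and 3.20 ± 0.27 without untreated replicate 2, where it passed (adjusted p = 0.0141 in edgeR), because that library held 103 CPM against 1.62 and 2.3 in its group mates. The list of SKN-1 targets, which act against oxidative stress, was higher as a set (23 genes, median 0.25, adjusted p = 0.00188, and 0.457 with an estimated correlation), with a median of 0.44 without untreated replicate 1 and 0.47 without jellyfish replicate 3. Its median lay inside the untreated range (-0.18 to 0.26) in jellyfish replicate 3 (0.12) and above it in jellyfish replicates 1 and 2 (0.56 and 0.36). With all libraries 0 members passed over all genes or adjusted over the list alone, while without untreated replicate 2, 4 passed adjusted over the list alone and DESeq2 called 4. With all libraries DESeq2 called gst-5 (1.43 ± 0.37) and gst-7 (0.68 ± 0.16), both glutathione transferase genes. The call of gst-5 was lost without jellyfish replicate 1, 2 or 3 (adjusted p up to 0.274), and that of gst-7 without untreated replicate 1 or 3 or jellyfish replicate 2 or 3 (up to 0.303). gst-4, the usual reporter of this pathway, had 15.6 ± 10.03 CPM in untreated and 42.4 ± 9.18 in treated worms and did not pass with all libraries (DESeq2 adjusted p = 0.155). DESeq2 called gst-4 without untreated replicate 2 (adjusted p = 0.00226) or without untreated replicate 3, and not in the other 4 fits that left out 1 library (adjusted p up to 0.607). The heat shock gene hsp-16.2 had a log2 fold change of -1.13 ± 1.34, from -1.72 without untreated replicate 2 to -0.61 without untreated replicate 3, and -0.74 without jellyfish replicate 1. The chaperone genes hsp-4 of the endoplasmic reticulum and hsp-6 of the mitochondria had -0.17 ± 0.27 (from -0.44 without untreated replicate 2 to 0.0602 without untreated replicate 1) and -0.29 ± 0.13 (-0.18 without jellyfish replicate 1). DESeq2 called hsp-16.2 and hsp-4, both lower, without untreated replicate 2 (adjusted p = 0.0376 and 0.0309) and in no other fit that left out 1 library. The peptide transporter gene pept-1 had 0.06 ± 0.39, from -0.30 without untreated replicate 2 to 0.37 without untreated replicate 1.

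The sperm list, 54 tested genes of which 1 had a log2 fold change above 0, had a median of -1.34 and adjusted p = 4.1e-18 in the set test, and 0.457 with an estimated correlation. No member passed in edgeR over all genes or adjusted over the list alone with all libraries, while 11 passed adjusted over the list alone without untreated replicate 3. DESeq2 called msp-19, msp-56 and msp-59, at 8.97 ± 2.88, 3.57 ± 0.414 and 8.38 ± 3.685 CPM in untreated worms. In treated worms they stood at 2.55 ± 1.34, 1.13 ± 0.278 and 2.21 ± 1.2 CPM (SD, n = 3). Of the 6 DESeq2 fits that left out 1 library, msp-56 passed in 6, msp-19 in 2 (not without untreated replicate 1 or any jellyfish replicate) and msp-59 in 1 (without untreated replicate 3). These are copies of the major sperm protein gene that are nearly identical, so reads may be split between them and the single values are uncertain. The oocyte list had a median of -0.35 over 31 genes (adjusted p = 9.86e-07, and 0.457 with an estimated correlation), with 0 members past the test. Adjusted over the list alone, 8 oocyte members passed without untreated replicate 2, all lower, and DESeq2 called 3. The 3 treated libraries lay below the 3 untreated ones in the median of the sperm and of the oocyte list. The 6 yolk protein genes had a median of -2.57 (adjusted p = 0.00135, and 0.457 with an estimated correlation), and vit-2 stood at 11.9 ± 3.71 CPM in untreated and 2.38 ± 2.01 in treated worms (SD, n = 3), with 0 members past the test. The vit-2 and msp levels were low in both groups, and 4 of 18 early embryo genes had enough reads to be tested. With the time of harvest unknown, these differences are not read as changes in reproducing adults. Adjusted over the list alone, 1 yolk gene passed without untreated replicate 1 or jellyfish replicate 2, and 2 without jellyfish replicate 3. The yolk medians of the groups overlapped, jellyfish replicate 3 (-1.16) lying above untreated replicate 1 (-1.51).

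**Figure D2:**
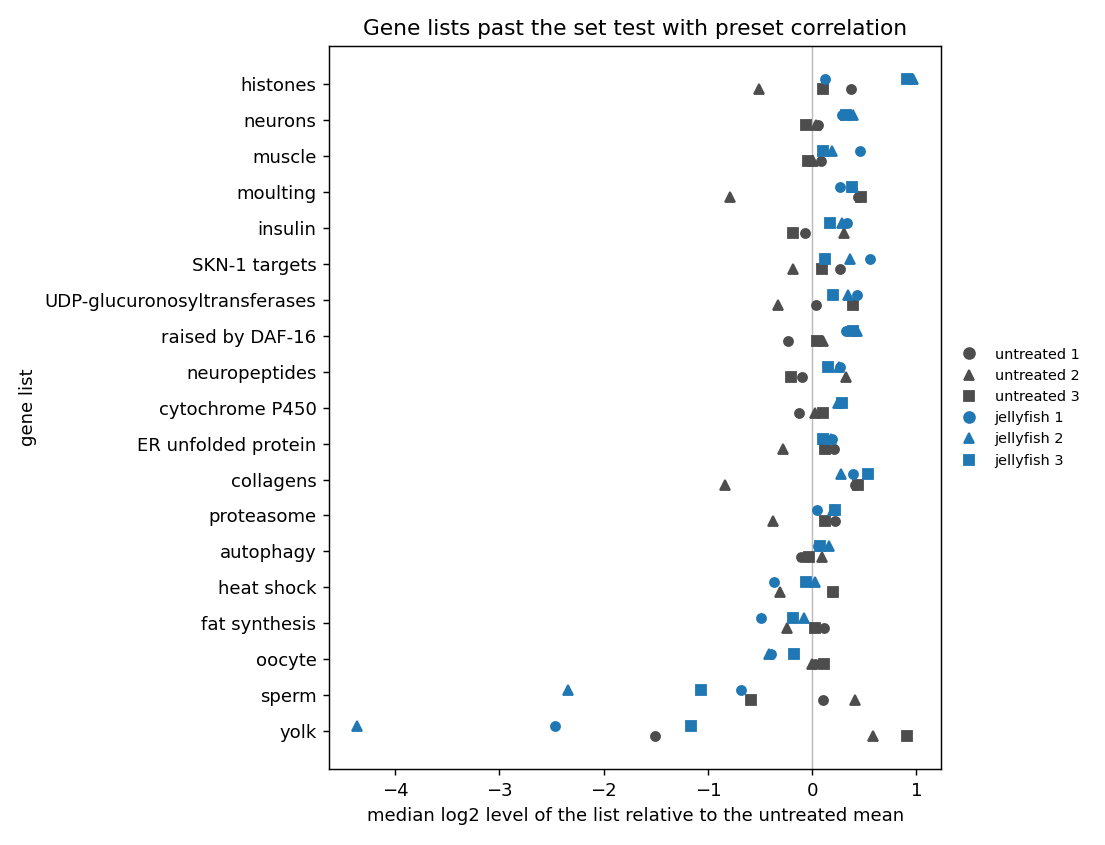
Median log2 level of the 19 gene lists that passed the set test with a preset correlation, in each library relative to the mean of the untreated libraries, with untreated libraries in grey, jellyfish libraries in blue and a symbol for each replicate number. The sperm medians of the treated libraries lie at -0.68, -2.34 and -1.07, below the untreated ones at 0.10, 0.41 and -0.58, and untreated replicate 2 lies apart for collagens at -0.83 and moulting at -0.79.

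The neuronal list had a median of 0.31 over 24 genes, of which 21 were above 0, with adjusted p = 2.98e-06 in the set test and 0.168 with an estimated correlation. That correlation was -0.0045, below the preset 0.01, so correlation between its genes does not explain the lost call. It was the 1 list that passed fry's test of movement in 1 direction with all libraries (adjusted p = 0.0208), but did not pass it without jellyfish replicate 1, 2 or 3 (0.174, 0.147 and 0.0893). Leaving out untreated replicate 2, 4 lists passed fry's test. The neuronal (0.0266), neuropeptide (0.038) and insulin signalling (0.0337) lists were higher. The list of genes lowered by DAF-16 (0.0266) was lower, with a mean log2 fold change of -0.43. Its median was -0.05, with 5 of 10 members above 0. The muscle list had a median of 0.27 with 24 of 24 genes above 0 (adjusted p = 9.86e-07, and 0.457 with an estimated correlation), and 0.17 without jellyfish replicate 1. In whole-worm libraries scaled to their size, change within neurons or muscle cannot be told apart from change in the share of other tissues. The germline lists were lower in the same comparison. Neuropeptide genes had a median of 0.21 over 61 genes and histone genes 0.67 over 42 (adjusted p = 7.24e-06 and 5.38e-05, and 0.635 and 0.584 with an estimated correlation). The groups overlapped in both lists. The neuropeptide median of untreated replicate 2 (0.32) lay above those of all 3 treated libraries (0.15 to 0.27), and the histone median of jellyfish replicate 1 (0.12) below that of untreated replicate 1 (0.37). The neuropeptide median was 0.39 without untreated replicate 2 and 0.11 without untreated replicate 3, and the histone median 0.44 without untreated replicate 2. With all libraries, no member of these 4 lists passed in edgeR over all genes or adjusted over the list alone. Without untreated replicate 2, 21 neuropeptide genes and 8 neuronal genes passed adjusted over the list alone, all higher, and DESeq2 called 10 and 7.

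In all, 19 of 35 lists fixed before the data were examined passed the set test with a preset correlation, 14 higher and 5 lower, and 0 passed with an estimated one. Every other grouping of the 6 libraries into 3 and 3 also passed lists with the preset correlation, from 7 to 17 of them. A pass at that setting is therefore weak evidence of a difference by treatment. The insulin signalling list (median 0.25), UDP-glucuronosyltransferases (0.23), autophagy (0.08), collagens (0.14), moulting (0.26), proteasome (0.13) and the endoplasmic reticulum stress list (0.16) were higher and the heat shock list (-0.27) lower, with adjusted p between 0.00695 and 0.0402 and between 0.557 and 0.652 with an estimated correlation. Without untreated replicate 2 the collagen, moulting, proteasome and endoplasmic reticulum stress lists no longer passed and their medians were -0.055, -0.0893, -0.00455 and -0.00525. Collagens and moulting also lost their call without jellyfish replicate 1 or 3, the endoplasmic reticulum stress list without jellyfish replicate 1 or 2 and the proteasome without jellyfish replicate 3 (adjusted p = 0.0575 to 0.103). The UDP-glucuronosyltransferase list lost its call without untreated replicate 2 or jellyfish replicate 1, heat shock, insulin and autophagy without untreated replicate 1 or 3, and insulin and heat shock also without jellyfish replicate 1 and autophagy also without jellyfish replicate 2. The UDP-glucuronosyltransferase median was 0.06 without untreated replicate 2, 0.39 without untreated replicate 3 and 0.14 without jellyfish replicate 1. The heat shock median was -0.15 without untreated replicate 3 and -0.13 without jellyfish replicate 1, and the autophagy median 0.18 without untreated replicate 2, 0.13 without jellyfish replicate 1 and 0.05 without jellyfish replicate 2. The collagen median was 0.30 without untreated replicate 1 and 0.43 without untreated replicate 3, the moulting median 0.435 without untreated replicate 3, and the proteasome median 0.22, 0.19 and 0.20 without untreated replicate 1, untreated replicate 3 and jellyfish replicate 1. Lists that did not pass included ribosomal proteins (median -0.02 over 74 genes, adjusted p = 0.321), the respiratory chain (0.01 over 63, 0.66), the mitochondrial unfolded protein response (-0.00065 over 17, 0.241), peptide transporters and digestive proteases (0.01 over 32, 0.67) and antioxidant enzymes (0.04 over 19, 0.389). Leaving out 1 library, the mitochondrial unfolded protein response list passed, lower, without untreated replicate 2 (median -0.10, adjusted p = 0.0102) and ribosomal proteins passed, lower, without untreated replicate 3 (-0.06, 0.0441), both with the preset correlation. Other lists gained a call in the same way. Among them, osmotic and metal response genes passed, higher, without untreated replicate 2 (0.23, 0.00478), and intestinal genes passed, higher, without untreated replicate 1 (0.22, 0.0178).

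Untreated replicate 2 differed from the other libraries more than the groups differed from each other. The first principal component held 49.9% of the variance and set it at 111.9, with the other libraries between -29.99 and -11.12. The second, with 22.5%, placed the 3 treated libraries at 16.13 to 37.18 and the 3 untreated ones at -65.25 to -2.11. The correlation of untreated replicate 2 with the others, across genes, was 0.903 to 0.92, while the other libraries correlated at 0.952 or more with each other. Untreated replicate 1 was as close to the treated libraries (0.966, 0.967 and 0.974 with jellyfish replicates 1, 2 and 3) as to untreated replicate 3 (0.966). In untreated replicate 2, 3715 genes differed by more than 2-fold from the mean of its group mates, against 665 to 2450 in the others. Compared with its group mates it had lower collagens (median log2 difference -1.25), moulting genes (-1.18) and histones (-0.76), and higher neuropeptides (0.48), insulin signalling genes (0.46), sperm genes (0.61) and genes of the response to intracellular pathogens (0.86). Of the 35 lists, 9 lay below and 7 above the central 95% of 10000 random lists matched on expression.

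**Figure D3:**
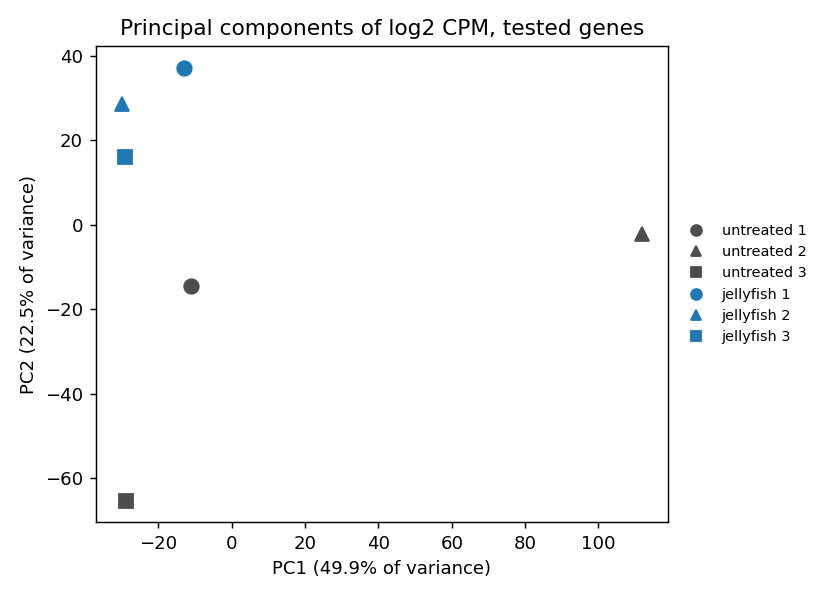
Principal components of log2 CPM over the tested genes, with untreated libraries in grey, jellyfish libraries in blue and a symbol for each replicate number. The first axis (49.9% of variance) separates untreated replicate 2 from the rest and the second (22.5%) places the 3 treated libraries above the 3 untreated ones.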

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

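The DESeq2, normalisation, filter, voom, FPKM and block fits and edgeR without each library were planned, and the robust, sample-weighted, DESeq2 leave-one-out, voom and robust fits without untreated replicate 2 were chosen after seeing the data. edgeR called 0 genes (1429 at an unadjusted p under 0.05) with all libraries, and 0 with other normalisations (RLE, upper quartile), with no filter or a CPM filter and with the robust fit, as did limma-voom and limma on log2(FPKM + 1), log2(FPKM + 0.1) and FPKM filtered at a mean of 1. DESeq2 called 169 genes, 76 higher, 93 lower and 133 over 2-fold and made 73 false calls in simulation, with each gene drawn on its own, against 10 in edgeR. Leaving out 1 library, edgeR called 0 to 16 genes (0 to 14 higher, 0 to 2 lower, 0 to 14 over 2-fold), the 16 without untreated replicate 2. Genes at an unadjusted p under 0.05 then ranged from 613 without jellyfish replicate 2 (751 expected with no difference) to 2376 without untreated replicate 2. limma-voom with sample weights called 7 (5 higher, 2 lower, 6 over 2-fold), limma-voom without untreated replicate 2 called 7 (5 higher, 2 lower, 7 over 2-fold) and robust edgeR without it 23 (19, 4 and 18). DESeq2 called 206 genes without untreated replicate 1 (129 higher, 77 lower, 155 over 2-fold), 618 without untreated replicate 2 (423, 195 and 214), 402 without untreated replicate 3 (137, 265 and 350), 146 without jellyfish replicate 1 (51, 95 and 121), 59 without jellyfish replicate 2 (37, 22 and 55) and 80 without jellyfish replicate 3 (42, 38 and 70). The lists past the set test numbered 13 to 19 in these settings, except 0 with an estimated correlation, with or without untreated replicate 2. The classes numbered 21 and ranged from 12 (without jellyfish replicate 1) to 31 (without jellyfish replicate 3), and 0 passed with an estimated correlation. The causes of these differences were not tested.

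Of 1374 alternative values of 53 named genes, 1070 kept their direction and side of the threshold, 276 passed it and 28 reversed. hsp-16.2 was 1.16 in limma-voom and 0.31 with log2(FPKM + 0.1), and hsp-4 ranged from -0.44 to 0.0602 in edgeR without each library, the highest without untreated replicate 1, where DESeq2 gave 0.0605. atgl-1, at -0.00391 with all libraries and from -0.0605 to 0.103 without each, was 0.00576 with no filter, 0.000796 in limma-voom, 0.00204 in the replicate block and 0.103, 0.000841 and 0.0323 in edgeR without untreated replicate 1, jellyfish replicate 2 or jellyfish replicate 3, with 0.101, 0.00203 and 0.028 in DESeq2. pept-1 ranged from -0.30 to 0.37 in edgeR without each library, and was -0.30 without untreated replicate 2 in edgeR, robust edgeR and voom, -0.31 in DESeq2 without it and -0.20 with sample weights. mtl-1 ranged from -1.55 to 3.20 in edgeR without each library and was 1.197 in limma-voom, 1.65 in the replicate block, 1.11 with log2(FPKM + 1), with or without the filter, 1.23 with log2(FPKM + 0.1), 2.76 with sample weights, and without untreated replicate 2 it was 3.20 in edgeR and robust edgeR, 3.19 in DESeq2 and 3.22 in voom. Without each library the list medians ranged from -0.055 to 0.43 for collagens, -0.0893 to 0.435 for moulting, -0.00525 to 0.23 for endoplasmic reticulum stress and -0.00455 to 0.22 for the proteasome, the lowest without untreated replicate 2. The causes of these reversals were not tested. Of 190 alternative values of the lists past the set test, 144 stayed, 42 lost the call and 4 reversed.

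Libraries of the same replicate number deviated from their group means with correlations of -0.08, -0.08 and 0.15. The highest with another number were 0.084, 0.21 and 0.0995, so replicate 3 was closest to its own number. Deviations within a group of 3 depend on each other, and untreated replicate 2 weighs on those of its group. A pairing by number is therefore neither shown nor excluded. With the replicate block edgeR called 0 genes, 979 had an unadjusted p under 0.05, and 18 lists and 23 classes passed the set test, autophagy being the list that lost its call (adjusted p = 0.0665). Depth limits the weakest transcripts alone, since 3 reads are 0.073 to 0.0954 CPM, and the median of all genes stayed between -0.03 and 0.03 (log2) in these settings.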

Other observations

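The enrichment tests, the DESeq2 fits without 1 library, the split counts of edgeR genes, the tests of depth, moulting phase and swapped labels, the sperm and oocyte tests, and the placement and copy tests of neighbours were chosen only after the result was seen. Classes of genes that share a locus-name prefix were also tested as sets, and some of their members are in the fixed lists, as gst-4, gst-5 and gst-7 are in the list of SKN-1 targets. With a preset correlation, 37 gst genes of glutathione conjugation had a median log2 fold change of 0.58 and 29 cest carboxylesterase genes 0.41 (camera adjusted p = 0.000206 and 5.75e-05, and 0.823 for both with an estimated correlation). The gcy class of guanylyl cyclases, many of them receptors of sensory neurons, had a median of 0.39 over 30 genes, and the npp class of nuclear pore genes -0.17 over 24 (adjusted p = 0.0114 and 0.00332, and 0.823 and 0.856 with an estimated correlation). Among the DESeq2 calls, the largest differences at a mean of 5 CPM or more also took in gpdh-1, which makes glycerol under osmotic stress (32.1 ± 4.09 CPM untreated, 8.53 ± 5.23 treated), the bZIP factor gene zip-10 (14.4 ± 4.63 and 4.34 ± 1.82), ugt-44 (33.3 ± 8.69 and 10.4 ± 2.15) and clec-47 (131 ± 26.97 and 51.8 ± 20.1), all lower. ndnf-1 (32.3 ± 6.56 and 85.5 ± 29.6) and txt-4, which encodes a lipase domain (2.44 ± 0.444 and 7.96 ± 3.75), were higher (SD, n = 3). Among called members of the fixed lists, the cadmium-responsive gene cdr-1 was higher too (2.14 ± 0.502 and 6.42 ± 0.0629). The DESeq2 calls of ugt-44, ndnf-1, txt-4 and cdr-1 passed in each of the 6 fits that left out 1 library. gpdh-1 lost its call without untreated replicate 2 or jellyfish replicate 2 (adjusted p up to 0.153), zip-10 without untreated replicate 1 or jellyfish replicate 1 or 3 (up to 0.0725) and clec-47 without jellyfish replicate 2 or 3 (up to 0.0672).

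Without untreated replicate 2, edgeR also called fmo-2, a flavin monooxygenase gene, cyp-37B1, clec-206, F17B5.1, C29F7.2 and the epoxide hydrolase gene W01A11.1, all higher. fmo-2 stood at 5.48 and 4.42 CPM in untreated replicates 1 and 3, 37.2 in untreated replicate 2 and 41.3 ± 14.5 (SD, n = 3) in treated worms. cyp-37B1 stood at 0.859, 0.809 and 10.2 CPM in the same untreated libraries and 7.18 ± 2.54 in treated worms. The DESeq2 calls without that library that were higher held 7 of 28 KEGG genes of pyruvate metabolism, where 0.878 were expected (hypergeometric adjusted p = 0.00158 over 101 pathways). Among them were the gluconeogenesis genes pck-1 and pyc-1, and icl-1, described above. Other pathways passed too, among them the worm longevity pathway (9 of 80, hypergeometric adjusted p = 0.0174) and FoxO signalling (7 of 59, 0.0298). Both of these held daf-2, akt-1, akt-2 and ist-1, so they are not separate evidence.

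acdh-1, a propionate breakdown gene and fixed readout, had 5 reads in the 6 libraries together, and ech-6 of the same fixed list had 7, all in jellyfish replicate 1. A later gene of that breakdown route, hphd-1, had 668 ± 309 CPM in untreated and 701 ± 234 in treated worms (SD, n = 3), and the list's 19 tested genes had a median of -0.04. ech-6 and hphd-1 were picked after their values were seen. Whether the near absence of acdh-1 and ech-6 reads reflects the animals, their strain or the annotation used for counting is not settled by these data, so the counts are not read as expression levels.

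The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real grouping gave 0 genes changed, higher, lower or over 2-fold in edgeR, as did the highest other (0), so 10 of the 10 splits gave as many. For genes at an unadjusted p under 0.05 the real grouping gave 1429 and the highest other 1135, for DESeq2 calls 169 and 45, and for lists past the set test 19 and 17, with 1 of the 10 splits as large in each case. For classes it gave 21 and the highest other 25, and 4 of the 10 splits gave as many. The other splits passed 7 to 17 lists and 13 to 25 classes, so many sets passed under any grouping.

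Untreated replicate 2 stood apart from the other 5 libraries. Its depth argues against a depth effect, since its total of 39.4 M counts (39433084) lies between those of the others (31447571 and 41112668). The Spearman correlation of its deviation with gene length, across genes, was -0.0542, against -0.0379 to 0.0395 in the treated libraries. Untreated replicate 3 gave 0.058, but its deviation is taken from a mean that holds untreated replicate 2. A correlation this small argues against a strong bias by gene length. It does not test RNA degradation as such. A swap of labels with a treated library would leave a treated library near the untreated ones, and 0 of the 3 were closer to untreated replicates 1 and 3 than to each other, while an exchange of all labels between the groups was not tested. Another phase of the moulting cycle stays open as a candidate explanation, since the median deviation of the moulting list, -1.18, lies below the central 95% of 10000 random lists matched on expression (-0.38 to 0.14). That explanation came from the same values, 16 of the 35 lists lay outside such a range in this library, so the test is not specific to moulting, and no independent measure of stage was at hand.

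The sperm and oocyte lists were lower in the treated libraries. Leaving out 1 library kept 74.5% or more of the median log2 fold change of each list, and the groups' library medians then still differed by 1.47 or more pooled SDs, which argues against 1 library as the whole cause. Reads shared between near-identical major sperm protein copies do not account for all of it, as the 26 sperm genes outside that class had a median of -1.08, with 25 below 0. Those 26 take in other numbered gene families, and sharing of reads within these was not tested. The spe class of sperm genes had a median of -0.66 over 21 genes. Without untreated replicate 2 that median was -0.31, and the class did not pass camera with the preset correlation (adjusted p = 0.0671). Differences in germline stage between cultures, unrelated to the peptide, cannot be told apart from an effect of treatment, because no independent measure of stage was at hand. The estimated correlation between genes was 0.62 in the sperm list and 0.19 in the oocyte list, and camera with it gave adjusted p = 0.457 for each. That p does not measure correlation, as the neuronal list, with an estimated correlation of -0.0045, also lost its call (0.168). An effect of the peptide on the germline therefore remains a hypothesis that these libraries leave untested.

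Neighbours were taken among the 14632 tested genes placed on the chromosomes of WBcel235, so untested genes may lie between them. Genes called by DESeq2 were neighbours in this sense more often than random placement gives. There were 10 such pairs with the same direction in each, where 1.94 were expected (permutation p = 0.0002, one-sided, 10000 draws). They took in F49C12.2 to F49C12.5, with 20, 0, 7 and 6 reads in the untreated libraries and 680, 94, 633 and 221 in the treated ones (F49C12.3 at least 29.6-fold higher, against 3 reads over the group), scl-12 and scl-13, and the P450 pairs cyp-34A9 and cyp-34A10, cyp-35A1 and cyp-35A2, and cyp-14A2 and cyp-14A3. Overlapping gene models were found in 0% of the pairs, which argues against reads counted for both genes of a pair. Similar neighbouring copies that share reads may account for part of it, as 50% of the pairs share a name prefix or description, and for the rest similarity was not measured. Shared regulation of neighbouring genes was not tested.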
